A study of Mus musculus with 16 samples.

How the data were processed

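RNA of flash-frozen livers of 16 C57BL/6 mice was sequenced, per the labels' protocols, after extraction with the Qiagen RNeasy mini kit and non-stranded library preparation by BGI. The mice form 4 groups of 4: CD_vehicle, CD_PFOA, HFD_vehicle and HFD_PFOA. Groups come from the labels of diet and treatment, and replicate numbers only follow the order of the records, so they pair no mice. Each mouse is a biological replicate per the design of the series. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, Trimmomatic 0.33, STAR 2.5.2b and featureCounts from Subread 1.6.0, with the genome build GRCm38 (mm10). The annotation release they used is not given in the sources used here. The deposited table holds raw counts per gene, which are whole numbers, for 53465 genes and 16 libraries; 25509 genes are 0 in every library.

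The number of counts per library ran from 14456524 to 25778125. Every column of the table was used in the comparisons, each matched to a mouse by its name. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 8.56 to 154 over pairs), so each was counted as 1 replicate. Reads carry no molecular identifiers, so the intervals and floors given cover counting error only. How reads shared between close relatives were assigned is not given in the sources used here.

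Genes were kept by filterByExpr of edgeR 4.0.16 with the 4 groups, which left 14998 genes. Libraries were scaled by TMM factors. All 16 libraries went into 1 edgeR quasi-likelihood fit with a mean per group (glmQLFit, glmQLFTest), with 12 residual degrees of freedom and a common biological coefficient of variation of 0.242. The contrasts tested were PFOA in CD, PFOA in HFD, HFD in vehicle, HFD in PFOA, and the interaction (PFOA in HFD minus PFOA in CD). P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes were called at adjusted p under 0.05. Fold changes are log2 with a prior count, and the SE is the absolute log2 fold change divided by the square root of the F statistic. CPM are counts per 1e+06 counts of the TMM-scaled library, given as mean ± SD over the 4 mice. Where a group had 0 counts, the fold is a lower bound against 3 counts summed over its 4 libraries, and with 1 to 3 counts a ratio with a 95% counting interval. The median of the other PPARA-responsive genes, with such genes at their bound, stayed at 1.67 in PFOA in CD and 1.39 in PFOA in HFD.

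The genes named in the text follow a rule fixed before the data were examined. For each contrast it takes the 6 largest rises and the 6 largest falls among genes with adjusted p under 0.05, mean CPM of at least 1, no overlap between the 2 groups and a named symbol (not for the interaction). To these it adds up to 4 members of each list with the smallest p and 24 index genes in every contrast. Limch1 and Ifih1 fall outside it in the places where they are said to be chosen after their values were seen.

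The 38 gene lists were also fixed before the data were examined, from general knowledge: peroxisomal fatty acid oxidation, mitochondrial fatty acid oxidation, microsomal fatty acid omega-oxidation, other PPARA-responsive genes, lipogenesis and triglyceride synthesis, cholesterol synthesis and bile acid synthesis and transport. Next were CAR and PXR responsive xenobiotic metabolism, NRF2 and glutathione genes, acute phase proteins, complement and coagulation, and cytokines and chemokines. Others were extracellular matrix and fibrosis, cell cycle, glucose metabolism, lipoprotein genes, unfolded protein response, p53 targets, male-biased and female-biased liver genes, circadian clock, and pericentral and periportal hepatocyte genes. The cell type lists were macrophage and Kupffer cells, neutrophils, T and NK cells, B cells, sinusoidal endothelium, stellate cells, cholangiocytes, adipocytes, erythroid cells, exocrine pancreas and skeletal muscle. The last 4 lists, by symbol pattern, were ribosomal proteins, nuclear oxidative phosphorylation genes, proteasome subunits and mitochondrially encoded genes. Exocrine pancreas and skeletal muscle had 1 tested member each, not called in any contrast, and no list test. The other 36 lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a contrast. The number called was 16 (PFOA in CD), 17 (PFOA in HFD), 20 (HFD in vehicle), 17 (HFD in PFOA) and 16 (interaction), and with an estimated correlation 7, 5, 0, 0 and 0. The test fry, which asks whether the genes of a list move one way on balance, called 19, 17, 19, 1 and 0, and its mixed form, for changes in either direction, 31, 29, 28, 3 and 14.

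Median, mean and camera direction differed in sign in 17 pairs of list and contrast, 0 of them called. They were p53 targets and nuclear oxidative phosphorylation in PFOA in CD; NRF2, clock, and T and NK cells in PFOA in HFD; and mitochondrial oxidation in HFD in vehicle. In HFD in PFOA they were peroxisomal oxidation, omega-oxidation, male-biased genes, adipocytes and the proteasome. In the interaction they were bile acids, lipoproteins, neutrophils, T and NK cells, endothelium and mitochondrially encoded genes.

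Gene positions come from GENCODE M21 on GRCm38; 14983 of the 14998 tested gene identifiers are in it, 13300 with the same version, as are all 406 named genes. Of these, 10 share over 25% of their exon length with another gene: Etfb, Fdps, Irs1, Ndufa13, Nr1i3, Psmd9, Sds, Serpinc1, Slc22a12 and Ugt1a5. The code was tested on simulated counts with 200 of 14998 genes changed. Of those changed 2-fold it called 55.2% in PFOA in CD, 52.2% in PFOA in HFD, 55.2% in HFD in vehicle and 44.8% in HFD in PFOA, and 34.3% or 31.3% in the interaction (HFD_PFOA or CD_vehicle changed). At 4-fold it called 78.8%, 75.8%, 77.3% and 74.2%, and 65.2% or 74.2% in the interaction; false calls were 8, 15, 5, 5, and 4 or 5 genes.

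Alternatives set before the data were examined were relative log expression factors, library totals, DESeq2 1.42.0, limma voom with quality weights, no filter, a mean CPM of at least 1, a fit of the 2 groups alone, and each library left out in turn. For the overlap it was an adjusted p under 0.01, and for the reversal it was a split of the HFD_vehicle libraries. Runs chosen after seeing the data are named as such below. Group labels were exchanged between libraries in 35 splits per contrast of 2 groups and in 100 draws for the interaction. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. Raw reads, liver histology and serum values were not analysed here.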

Results

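Liver RNA from C57BL/6 mice was sequenced in 4 groups of 4 mice: control diet (CD) or high-fat diet (HFD), each given vehicle or perfluorooctanoic acid (PFOA). The diets ran for 16 weeks before treatment and for the 8 weeks of treatment, and livers were taken at an age of 29 to 30 weeks. The groups ask what PFOA does to gene activity in lean liver and in diet-induced fatty liver. The sex of the mice and the dose of PFOA are not given in the sources used here. Each of the 16 libraries comes from a separate mouse. Of 53465 genes in the table, 14998 had enough counts to be tested, and these held 99.9% of all counts.

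Livers given PFOA separated from livers given vehicle on both diets, and the diets separated more under vehicle than under PFOA. The first principal component held 32.0% of the variance and ran from −72.7 to −18.4 in the vehicle libraries and from 31.6 to 50.9 in the PFOA libraries. On the second, with 13.7%, the HFD_vehicle libraries lay at −47.4 to −32.6 and the libraries CD_vehicle 1 to 3 at 18.8 to 50.5. Library CD_vehicle 4 lay apart from these at −16.7. Between libraries of one group, the mean correlation of log2 CPM across genes was 0.956 in CD_vehicle, 0.960 in CD_PFOA, 0.971 in HFD_vehicle and 0.970 in HFD_PFOA, and genes are not independent replicates.

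**Figure D1:**
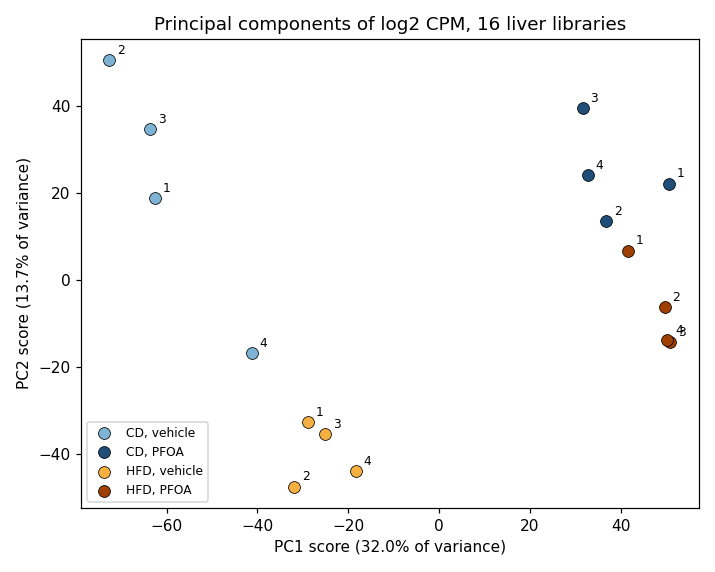
Principal components of log2 CPM (counts per 1e+06 counts of the scaled library) of the 14998 tested genes. Each point is 1 library (1 mouse), coloured by group, with component 1 on the horizontal axis and component 2 on the vertical axis. Vehicle and PFOA libraries lie on opposite sides of component 1, and CD_vehicle 4 lies at −16.7 on component 2, between the other CD_vehicle libraries and the HFD_vehicle libraries.

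PFOA in control-diet livers strongly raised genes of fatty acid breakdown and drug metabolism and lowered genes for secreted plasma proteins. Ehhadh, a peroxisomal beta-oxidation enzyme, rose from 624 ± 127 CPM (mean ± SD, n = 4) in CD_vehicle to 15408 ± 1841 CPM in CD_PFOA, a 24.7-fold rise (log2 fold change 4.63 ± 0.16 (SE), edgeR adjusted p = 1.37e-13). Cyp4a10, a fatty acid omega-hydroxylase, rose from 414 ± 77.9 to 6642 ± 681 CPM (16.0-fold, log2 fold change 4.00 ± 0.17, edgeR adjusted p = 4.05e-12). Cyp2b10, the classic target of the receptor CAR, rose 269-fold from 1.18 ± 0.714 to 315 ± 68.3 CPM (log2 fold change 8.07 ± 0.44). Slco1a1, an organic anion transporter, fell from 228.6 ± 125 to 2.89 ± 0.793 CPM, 79.0-fold lower (log2 fold change -6.30 ± 0.71, edgeR adjusted p = 1.82e-06). In all, edgeR called 3656 of 14998 genes at adjusted p < 0.05, 1763 higher and 1893 lower, of which 738 and 551 changed at least 2-fold. Scaling by library totals gave 3536 calls, with more of them higher (2160) than lower (1376).

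**Figure D2:**
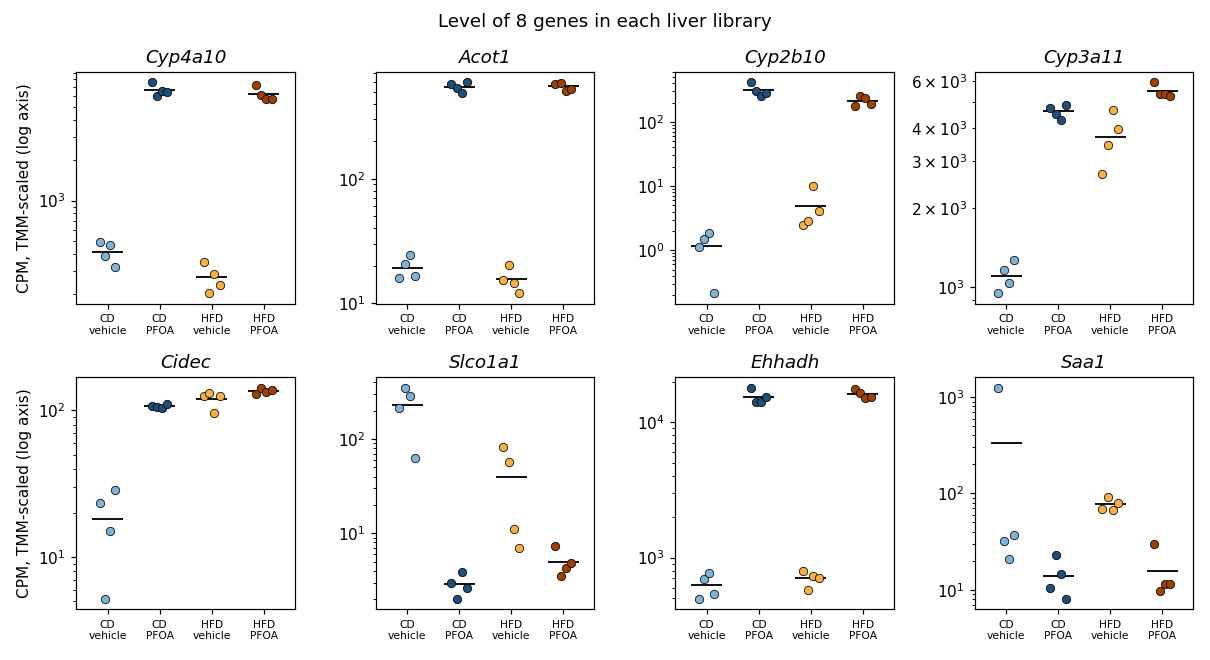
CPM on a log axis for 8 genes (Cyp4a10, Acot1, Cyp2b10, Cyp3a11, Cidec, Slco1a1, Ehhadh, Saa1) in the 4 groups; each point is 1 library and each line the mean of 4. Cyp4a10 went from 414 to 6642 CPM with PFOA on CD and from 267 to 6206 CPM on HFD, and Saa1 in CD_vehicle rests on 1 library at 1255 CPM.

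The main genes named here map, in GENCODE M21 on GRCm38, as follows. Cyp4a10 (ENSMUSG00000066072.13) lies on chromosome 4 at 115518264–115533649, Acot1 (ENSMUSG00000072949.6) on chromosome 12 at 84009490–84018371 and Ehhadh (ENSMUSG00000022853.6) on chromosome 16 at 21761287–21787807. Cyp2b10 (ENSMUSG00000030483.14) lies on chromosome 7 at 25897620–25926624, Cyp3a11 (ENSMUSG00000056035.8) on chromosome 5 at 145854426–145879964 and Slco1a1 (ENSMUSG00000041698.11) on chromosome 6 at 141907282–141946962. Cidec (ENSMUSG00000030278.11) lies on chromosome 6 at 113424634–113435760, Lpl (ENSMUSG00000015568.16) on chromosome 8 at 68880491–68907448 and Tm7sf2 (ENSMUSG00000024799.14) on chromosome 19 at 6062821–6068373. The libraries were not stranded, so reads of overlapping genes and of close relatives such as the Cyp4a, Cyp2b, Cyp3a, Mup, Gstm and Ugt1a families cannot be fully told apart.

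On the control diet, genes that break down fatty acids rose nearly throughout with PFOA. Of the peroxisomal fatty acid oxidation list, 16 of 18 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 1.35 (limma camera adjusted p = 5.18e-36, or 0.00103 with an estimated correlation). Eci2 (1.498 ± 0.09), Ech1 (1.27 ± 0.09) and the peroxisome division factor Pex11a (1.89 ± 0.13) rose with Ehhadh (log2 fold change ± SE, as in all such brackets that follow). Of the mitochondrial list, 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone) (camera adjusted p = 6.30e-33, or 0.00178 with an estimated correlation), among them Acot2 (5.19 ± 0.21), Hadhb (1.66 ± 0.09) and Acadl (1.26 ± 0.08). Of the omega-oxidation list, 8 of 10 rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 4.74e-20, or 0.00235 with an estimated correlation): Cyp4a31 rose 162-fold, while Cyp4f14 fell 14.3-fold. Of the other genes known to respond to the receptor PPARA, 20 of 23 rose and 0 fell (20 and 1 adjusted over the list alone) (camera adjusted p = 7.45e-39, or 3.04e-04 with an estimated correlation). They included Acot1 (28.4-fold), the pyruvate dehydrogenase kinase Pdk4 (7.99-fold), the fatty acid transporter Cd36 (3.38-fold), and the lipid droplet genes Plin2 (2.45-fold) and Cidec (5.90-fold). Otop1, a proton channel with 0 counts in all 4 CD_vehicle libraries, reached 19.7 ± 2.23 CPM in CD_PFOA. That is at least 594-fold against a floor of 3 counts summed over the 4 libraries, and Fabp3, a fatty acid binding protein, was at least 323-fold higher on the same floor.

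Drug-metabolism genes rose with PFOA on the control diet. Of the CAR and PXR list, 14 of 20 rose and 0 fell (14 and 0 adjusted over the list alone) (camera adjusted p = 8.04e-13, or 0.0244 with an estimated correlation), among them Cyp2b10, Cyp3a11 (4.18-fold), Cyp2c55 (3.33 ± 0.21) and the P450 reductase Por (2.05 ± 0.16). Of the NRF2 and glutathione list, 9 of 21 rose and 2 fell (9 and 3 adjusted over the list alone) (camera adjusted p = 0.00388, or 0.522 with an estimated correlation), with rises of Gstm3 (2.51 ± 0.39) and Ephx1 (1.46 ± 0.10). Of the bile acid list, 5 of 21 rose and 10 fell (5 and 10 adjusted over the list alone), and the list test gave camera adjusted p = 0.112, or 0.563 with an estimated correlation. Without CD_vehicle 4 the list was called lower (median −0.56, camera adjusted p = 0.0344, or 0.417 with an estimated correlation). The efflux pump Abcc4 rose 24.8-fold (log2 fold change 4.63, and 5.33 without CD_vehicle 4) while Slco1a1 fell, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.01 ± 0.43. Female-biased liver genes rose and male-biased ones fell in the same livers. Of the female-biased list, 9 of 14 rose and 1 fell (10 and 1 adjusted over the list alone) (camera adjusted p = 1.84e-09, or 0.0393 with an estimated correlation). For the male-biased list, 1 of 19 rose and 12 fell (1 and 14 adjusted over the list alone) (camera adjusted p = 7.27e-08, or 0.308 with an estimated correlation), with Mup21 at -2.54 ± 0.27 and Mup20 at -2.09 ± 0.23. Library CD_vehicle 4 stood 0.97 log2 below the other CD_vehicle libraries in the median of the male-biased list and 0.82 above in that of the female-biased list, where CD_vehicle 1 stood at −1.19 log2. Both calls held without either library. The lists share members: Slco1a1 and Cyp7b1 (bile acid and male-biased), C6 (complement and male-biased), Cyp2b9 and Cyp2b13 (CAR and PXR, and female-biased), Acot3 and Abcd2 (peroxisomal and female-biased) and Cyp4a14 (omega-oxidation and female-biased).

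Genes for plasma proteins, protein folding and glucose metabolism fell with PFOA on the control diet. Of the complement and coagulation list, 0 of 32 rose and 30 fell (0 and 30 adjusted over the list alone) (camera adjusted p = 3.27e-23, or 0.0558 with an estimated correlation), among them the coagulation factor F11 (-2.41 ± 0.17) and the complement protease C1s1, which went from 337 ± 24.9 to 148 ± 7.79 CPM (-1.18 ± 0.09). Of the acute phase list, 0 of 20 rose and 12 fell (0 and 13 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 4.80e-05, or 0.563 with an estimated correlation). Serpina3m (-1.83 ± 0.16) and Crp (-0.93 ± 0.14) fell in every leave-one-out fit, but Saa1 moved from -4.59 to −1.10 and the median of the list to −0.35 without CD_vehicle 1. In that library all 20 acute phase genes lay above the other CD_vehicle libraries, by a median of 1.75 log2. Of the unfolded protein response list, 2 of 18 rose and 15 fell (2 and 15 adjusted over the list alone) (camera adjusted p = 2.64e-06, or 0.434 with an estimated correlation): the folding enzyme Pdia6 (-1.46 ± 0.17) and Manf (-2.08 ± 0.29) fell and the pseudokinase Trib3 rose 7.83-fold. CD_vehicle 1 also stood 0.96 log2 above the other CD_vehicle libraries in the median of this list, and 0.23 in that of complement and coagulation. CD_vehicle 4 stood at −0.32 in the latter, with 0 of 32 members higher, and CD_vehicle 2 at −0.55 in the former. Of the glucose metabolism list, 0 of 16 rose and 10 fell (0 and 11 adjusted over the list alone) (camera adjusted p = 2.68e-07, or 0.00597 with an estimated correlation), among them the gluconeogenic enzyme Fbp1 (-1.06 ± 0.09), pyruvate kinase Pklr (-1.65 ± 0.20) and the glucose transporter Slc2a2 (-1.27 ± 0.16).

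Lipid synthesis genes went both ways on the control diet. Of the lipogenesis and triglyceride list, 4 of 21 rose and 9 fell (4 and 11 adjusted over the list alone) (camera adjusted p = 0.425, or 0.831 with an estimated correlation): Scd2 rose 22.1-fold and Mogat1 10.2-fold, while the phosphatidate phosphatase Lpin1 (-2.31 ± 0.33), the lipogenic transcription factor Srebf1 (-0.72 ± 0.18) and fatty acid synthase Fasn (-1.05 ± 0.29) fell. Scd1 had -0.34 ± 0.14 and was not called. Without CD_vehicle 1 the list was called lower (median −0.62, camera adjusted p = 0.00111, or 0.495 with an estimated correlation). Of the cholesterol synthesis list, 0 of 24 rose and 7 fell (0 and 7 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.00388, or 0.643 with an estimated correlation). The median was −0.25 without CD_vehicle 4 and the call ended (camera adjusted p = 0.151); in that library 23 of 24 members lay above the other CD_vehicle libraries, by a median of 0.91 log2. CD_vehicle 1 stood 0.99 log2 below the others in the same median. Mvd (-1.57 ± 0.39) and Insig1 (-0.79 ± 0.13) fell. Of the lipoprotein list, 4 of 20 rose and 7 fell (4 and 10 adjusted over the list alone) (camera adjusted p = 0.275, or 0.563 with an estimated correlation): lipoprotein lipase Lpl rose 13.8-fold from 35.5 ± 12.54 to 489 ± 24.0 CPM, and Apoa5 (-1.05 ± 0.14) and Apoc3 (-0.94 ± 0.13) fell.

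No list of cell type markers was called with PFOA on the control diet. Of the macrophage markers, 1 of 17 rose and 0 fell (1 and 0 adjusted over the list alone) (camera adjusted p = 0.499). For the sinusoidal endothelial markers, 5 of 14 rose and 1 fell (5 and 1 adjusted over the list alone) (camera adjusted p = 0.293), and for the stellate markers 1 of 13 rose and 1 fell (1 and 1 adjusted over the list alone) (camera adjusted p = 0.765). Of the B cell markers, 0 of 10 rose and 2 fell (0 and 2 adjusted over the list alone) (camera adjusted p = 0.515). These falls rest on CD_vehicle 4, which stood 4.57 log2 above the other CD_vehicle libraries in the median of 4 B cell genes. Without it Igkc went from -3.29 to −0.25 (edgeR adjusted p = 0.695) and Jchain from -2.98 to −0.23 (edgeR adjusted p = 0.830). Of the cholangiocyte markers, 0 of 11 rose and 1 fell (0 and 0 adjusted over the list alone), and of the erythroid markers 0 of 6 rose and 1 fell (0 and 1 adjusted over the list alone) (camera adjusted p = 0.426 and 0.669). No member of the neutrophil and T and NK lists was called (camera adjusted p = 0.583 and 0.975). Of the adipocyte markers, 3 of 6 rose and 1 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.0877), with Fabp4 at 1.90 ± 0.23 and Car3 at -2.29 ± 0.19. Of the cytokine list, 2 of 19 rose and 0 fell (1 and 0 adjusted over the list alone) (camera adjusted p = 0.0616); the interleukin-1 receptor antagonist Il1rn rose 7.16-fold. Of the matrix and fibrosis list, 5 of 23 rose and 1 fell (5 and 1 adjusted over the list alone) (camera adjusted p = 0.156), with rises of Col4a1 (0.89 ± 0.15) and Col4a2 (1.08 ± 0.14); without CD_vehicle 4 the list was called higher (median 0.52, camera adjusted p = 7.36e-04, or 0.259 with an estimated correlation). The cytokine list was then called higher too (0.68, camera adjusted p = 0.00578, or 0.149 with an estimated correlation). Of the cell cycle list, 7 of 25 rose and 0 fell (7 and 0 adjusted over the list alone) (camera adjusted p = 0.00520, or 0.556 with an estimated correlation), including Birc5 (1.91 ± 0.54). CD_vehicle 4 stood above the other CD_vehicle libraries in the medians of the cell cycle (1.02 log2), macrophage (1.04 log2) and matrix (0.88 log2) lists.

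In high-fat-diet livers, PFOA raised the same classes of oxidation genes and lowered plasma protein genes, starting from livers already changed by the diet. Acot1, an acyl-CoA thioesterase, rose from 15.5 ± 3.39 CPM (n = 4) in HFD_vehicle to 551 ± 38.5 CPM in HFD_PFOA (35.5-fold, log2 fold change 5.15 ± 0.16, edgeR adjusted p = 1.07e-13). Cyp4a10 rose 23.2-fold, Ehhadh 23.0-fold and Cyp2b10 46.0-fold. Ntrk2, a neurotrophin receptor, fell from 50.7 ± 16.7 to 0.706 ± 0.397 CPM (-6.14 ± 0.45). Otop1, with 0 counts in the HFD_vehicle libraries, reached 42.2 ± 13.1 CPM, at least 1214-fold above the floor of 3 counts. Fabp3 had 3 counts in HFD_vehicle and 2433 in HFD_PFOA, a ratio of 708 (242 to 3433, a 95% interval of counting error alone). That ratio rests on HFD_vehicle 2, without which the log2 fold change of Fabp3 went from 9.25 to 12.17. edgeR called 2476 of 14998 genes, 1290 higher and 1186 lower.

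Fatty acid oxidation genes rose as a group with PFOA on HFD. Of the peroxisomal list, 15 of 18 rose and 1 fell (17 and 1 adjusted over the list alone) (camera adjusted p = 1.36e-48, or 1.37e-04 with an estimated correlation). For the mitochondrial list, 19 of 20 rose and 0 fell (20 and 0 adjusted over the list alone) (camera adjusted p = 3.66e-41, or 4.52e-04 with an estimated correlation). Omega-oxidation genes moved likewise: 8 of 10 rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 7.60e-33, or 1.50e-04 with an estimated correlation). Abcd3 (1.76 ± 0.11), Hadhb (1.55 ± 0.09) and Cyp4a31 (155-fold) rose, and Cyp4f14 (-3.03 ± 0.17) fell. Of the other PPARA-responsive genes, 19 of 23 rose and 2 fell (20 and 2 adjusted over the list alone) (camera adjusted p = 8.09e-45, or 9.70e-05 with an estimated correlation), with Pdk4 15.8-fold and Plin2 2.61-fold higher. Cidec, already at 119.85 ± 15.8 CPM in HFD_vehicle, was at 136 ± 5.98 CPM in HFD_PFOA and was not called (0.18 ± 0.27). Of the CAR and PXR list, 9 of 20 rose and 0 fell (12 and 0 adjusted over the list alone) (camera adjusted p = 4.31e-09, or 0.0510 with an estimated correlation), with rises of Cyp2c55 (2.63 ± 0.20), Cyp2c29 (2.41 ± 0.24) and Cyp3a11 (1.49-fold). Of the NRF2 list, 2 of 21 rose and 3 fell (2 and 4 adjusted over the list alone) (camera adjusted p = 0.729), with Ephx1 up (0.63 ± 0.09) and Gstm2 down (-1.58 ± 0.25).

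Plasma protein and folding genes fell with PFOA on HFD. Of the complement and coagulation list, 0 of 32 rose and 18 fell (0 and 22 adjusted over the list alone) (camera adjusted p = 5.50e-13, or 0.205 with an estimated correlation), among them C9 (-2.11 ± 0.26) and C1s1 (-1.13 ± 0.08). For the acute phase list, 0 of 20 rose and 4 fell (0 and 4 adjusted over the list alone) (camera adjusted p = 6.52e-04, or 0.634 with an estimated correlation), among them Serpina3m (-1.74 ± 0.16) and Itih4 (-1.23 ± 0.33). Of the unfolded protein response list, 1 of 18 rose and 14 fell (1 and 14 adjusted over the list alone) (camera adjusted p = 1.14e-05, or 0.463 with an estimated correlation), with falls of Herpud1 (-1.39 ± 0.13) and Pdia6 (-1.20 ± 0.17). Of the glucose metabolism list, 0 of 16 rose and 8 fell (0 and 8 adjusted over the list alone) (camera adjusted p = 2.60e-06, or 0.0165 with an estimated correlation), with Slc2a2 (-1.40 ± 0.16) lower. HFD_PFOA 1 stood above the other HFD_PFOA libraries in the medians of the complement (0.35 log2, 32 of 32 members), acute phase (0.47) and unfolded protein response (0.34) lists, and each call held without it. Of the bile acid list, 3 of 21 rose and 9 fell (4 and 10 adjusted over the list alone) (camera adjusted p = 0.0352, or 0.463 with an estimated correlation): Abcc4 rose (2.74 ± 0.35) and the steroid reductase Akr1d1 fell (-1.44 ± 0.23). That call ended without HFD_PFOA 2 (camera adjusted p = 0.0503) or 4 (0.0664). Cyp7a1 fell (-1.93, or -1.14 without HFD_vehicle 3), a call that ended with limma voom (adjusted p = 0.054). Of the lipoprotein list, 4 of 20 rose and 8 fell (4 and 8 adjusted over the list alone) (camera adjusted p = 0.299), with Lpl (2.15 ± 0.18) and Pltp (1.999 ± 0.20) higher and Apoa5 lower (-0.99 ± 0.14).

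The lipid synthesis lists were not called with PFOA on HFD. Of the cholesterol synthesis list, 6 of 24 rose and 0 fell (6 and 0 adjusted over the list alone) (camera adjusted p = 0.0876), with Hsd17b7 (0.91 ± 0.18), Lss (0.87 ± 0.20) and Tm7sf2 (0.58 ± 0.16) higher. The call of Tm7sf2 ended without HFD_vehicle 2 (edgeR adjusted p = 0.0667) and HFD_PFOA 1 (0.0545). Of the lipogenesis list, 6 of 21 rose and 1 fell (7 and 3 adjusted over the list alone) (camera adjusted p = 0.120): Scd2 (3.53 ± 0.39) and the carbohydrate-response factor Mlxipl (1.02 ± 0.14) rose, Lpin1 fell (-3.10 ± 0.34) and Fasn had -0.28 ± 0.29. Of the female-biased list, 7 of 14 rose and 0 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 1.47e-08, or 0.0510 with an estimated correlation). For the male-biased list, 1 of 19 rose and 6 fell (2 and 7 adjusted over the list alone) (camera adjusted p = 0.00499, or 0.634 with an estimated correlation), with Mup20 at -3.15 ± 0.24. HFD_PFOA 1 stood 0.96 log2 above the other HFD_PFOA libraries in the median of that list, and the call held without it. In the female-biased list HFD_vehicle 3 stood at 0.71 log2, and that call held as well. Of the stellate markers, 0 of 13 rose and 3 fell (0 and 3 adjusted over the list alone) (camera adjusted p = 0.0342, or 0.554 with an estimated correlation). HFD_PFOA 3 stood at −0.40 log2 in that list, and without it the call ended (camera adjusted p = 0.1004). Of the matrix list, 1 of 23 rose and 4 fell (2 and 5 adjusted over the list alone) (camera adjusted p = 0.147), with Lum (-1.11 ± 0.28) lower. No macrophage, neutrophil, T and NK, B cell, erythroid or cell cycle marker was called by edgeR (camera adjusted p = 0.144, 0.637, 0.834, 0.7001, 0.255 and 0.121). Of the endothelial markers, 2 of 14 rose and 0 fell (2 and 0 adjusted over the list alone), and of the cholangiocyte markers 0 of 11 rose and 2 fell (0 and 2 adjusted over the list alone) (camera adjusted p = 0.255 and 0.141). For the adipocyte markers, 3 of 6 rose and 2 fell (3 and 3 adjusted over the list alone), and for the cytokine list 1 of 19 rose and 0 fell (1 and 0 adjusted over the list alone) (camera adjusted p = 0.228 and 0.637).

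The PFOA responses on the 2 diets overlapped far beyond independent lists. Of the genes called on either diet, 1774 were called in the same direction on both, 915 higher and 859 lower, where independent lists of these sizes would share 152 and 150. Only 8 genes were called in opposite directions. The log2 fold changes correlated across all 14998 genes (Pearson r = 0.68, Spearman rho = 0.57), which describes genes, not independent replicates.

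**Figure D3:**
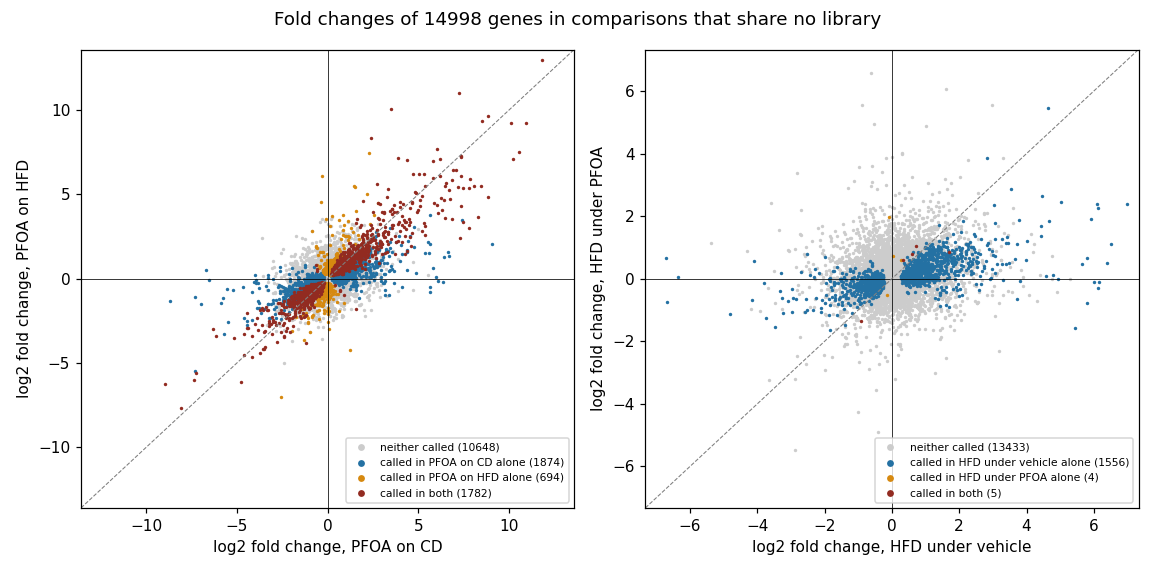
Log2 fold changes of the 14998 tested genes, 1 point per gene, coloured by where edgeR called it: left, PFOA on CD (horizontal axis) against PFOA on HFD (vertical axis); right, HFD under vehicle (horizontal axis) against HFD under PFOA (vertical axis), with equal changes on the dashed line. On the left 1774 genes were called in the same direction in both comparisons, and on the right 5, with 1556 called under vehicle alone.

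The high-fat diet under vehicle raised macrophage and matrix genes and lowered genes of cholesterol synthesis and lipogenesis. Trem2, a receptor of lipid-associated macrophages, rose from 0.633 ± 0.473 CPM (n = 4) in CD_vehicle to 6.82 ± 1.72 CPM in HFD_vehicle (10.7-fold, log2 fold change 3.42 ± 0.59, edgeR adjusted p = 0.00114). Col3a1, a fibrillar collagen, went from 32.5 ± 15.5 to 90.6 ± 10.95 CPM (2.79-fold, log2 fold change 1.48 ± 0.21, edgeR adjusted p = 3.09e-04). Cidec, which enlarges lipid droplets, rose 6.62-fold from 18.1 ± 10.2 CPM (2.73 ± 0.29). Tm7sf2, a sterol reductase, fell from 73.5 ± 10.1 to 21.5 ± 4.19 CPM, 3.41-fold lower (-1.77 ± 0.16, edgeR adjusted p = 4.54e-06). edgeR called 1561 of 14998 genes, 779 higher and 782 lower, and 382 and 128 of them changed at least 2-fold.

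Inflammatory, matrix and proliferation genes were higher on HFD under vehicle. Of the macrophage markers, 10 of 17 rose and 0 fell (11 and 0 adjusted over the list alone) (camera adjusted p = 5.88e-10, or 0.2496 with an estimated correlation), among them Ccr2 (1.66 ± 0.30) and Cd68 (1.58 ± 0.28). Of the matrix list, 16 of 23 rose and 0 fell (20 and 1 adjusted over the list alone) (camera adjusted p = 4.58e-16, or 0.0566 with an estimated correlation), among them Col1a1 (3.35-fold) and Col6a3 (1.30 ± 0.25). Of the stellate markers, 4 of 13 rose and 0 fell (5 and 0 adjusted over the list alone) (camera adjusted p = 1.02e-04, or 0.2496 with an estimated correlation), with Pdgfrb at 0.89 ± 0.18. Of the cytokine list, 4 of 19 rose and 0 fell (6 and 0 adjusted over the list alone) (camera adjusted p = 1.42e-07, or 0.0566 with an estimated correlation), including Il1rn (2.21 ± 0.25) and the adhesion molecule Vcam1 (1.44 ± 0.29). Of the cell cycle list, 8 of 25 rose and 0 fell (13 and 0 adjusted over the list alone) (camera adjusted p = 1.92e-07, or 0.2496 with an estimated correlation), including Birc5 (2.25 ± 0.54). CD_vehicle 4 stood above the other CD_vehicle libraries in the macrophage, matrix and cell cycle lists by the medians given for PFOA on the control diet. Without it the list medians were 1.29, 1.36 and 1.10, and that of the cytokine list 0.89. CD_vehicle 1 stood at −0.60 log2 in the matrix and −0.51 in the stellate list, and CD_vehicle 4 at 0.36 in the latter, and those calls held without either. Of the cholangiocyte markers, 1 of 11 rose and 0 fell (4 and 0 adjusted over the list alone), with osteopontin Spp1 at 1.68 ± 0.26 (camera adjusted p = 0.0272, or 0.270 with an estimated correlation). That call ended without CD_vehicle 1 (camera adjusted p = 0.0531), without HFD_vehicle 4 (0.0613) and with library totals as the scaling (0.0908). Of the endothelial markers, 2 of 14 rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.645). For the B cell markers, with CD_vehicle 4 apart as described for PFOA on the control diet, 0 of 10 rose and 1 fell (0 and 3 adjusted over the list alone), and for the adipocyte markers 2 of 6 rose and 0 fell (2 and 0 adjusted over the list alone) (camera adjusted p = 0.332 and 0.222). No neutrophil, T and NK or erythroid marker was called by edgeR (camera adjusted p = 0.0579, 0.574 and 0.921). Without CD_vehicle 1 the neutrophil list was called higher (median 1.48, camera adjusted p = 0.0434, or 0.331 with an estimated correlation).

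Sterol and fatty acid synthesis genes were lower on HFD under vehicle. Of the cholesterol synthesis list, 0 of 24 rose and 21 fell (0 and 23 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 8.51e-30, or 0.0566 with an estimated correlation). Pmvk (-1.39 ± 0.19), Stard4 (-1.21 ± 0.17) and Ebp (-0.70 ± 0.09) fell. CD_vehicle 4 stood 0.91 log2 above, and CD_vehicle 1 0.99 log2 below, the other CD_vehicle libraries in the median of this list; without the first the list median was −0.98, without the second −1.38. Of the lipogenesis list, 1 of 21 rose and 10 fell (2 and 13 adjusted over the list alone) (camera adjusted p = 5.94e-06, or 0.298 with an estimated correlation): Acss2 (-2.07 ± 0.28), ATP citrate lyase Acly (-1.71 ± 0.34) and Pnpla3 (-2.55 ± 0.53) fell, while Scd1 and Srebf1 had -0.14 ± 0.14 and -0.11 ± 0.18. CD_vehicle 1 stood at −1.046 log2 and CD_vehicle 4 at 0.72 against the other CD_vehicle libraries in the median of that list. The list median was −0.58 without the first and −0.47 without the second, and the call held. Of the other PPARA-responsive genes, 5 of 23 rose and 3 fell (6 and 4 adjusted over the list alone) (camera adjusted p = 0.0906), with rises of Plin4 (2.05 ± 0.30) and Cidea (1.62 ± 0.38). Without CD_vehicle 4 that list was called higher (median 0.17, camera adjusted p = 0.0233, or 0.328 with an estimated correlation). Of the omega-oxidation list, 1 of 10 rose and 4 fell (1 and 5 adjusted over the list alone) (camera adjusted p = 0.0115, or 0.270 with an estimated correlation), with Cyp4a12a at -1.37 ± 0.24. Of the peroxisomal and mitochondrial lists 0 members rose and 1 fell, Acot3 (-1.36 ± 0.33), a call that ended without HFD_vehicle 2 (edgeR adjusted p = 0.0501) and with 2 groups in the fit (0.0823) (camera adjusted p = 0.643 and 0.875). Of the lipoprotein list, 2 of 20 rose and 8 fell (2 and 9 adjusted over the list alone) (camera adjusted p = 0.146), with Lpl (1.89 ± 0.18) and the cholesterol exporter Abcg1 (1.62 ± 0.19) higher and Apom (-0.95 ± 0.11) lower.

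Complement, male-biased and NRF2 genes also differed with diet under vehicle. Of the complement and coagulation list, 0 of 32 rose and 17 fell (0 and 20 adjusted over the list alone) (camera adjusted p = 5.10e-12, or 0.2496 with an estimated correlation), among them F7 (-0.94 ± 0.16) and Mbl2 (-0.84 ± 0.15). Of the acute phase list, 0 of 20 rose and 6 fell (0 and 9 adjusted over the list alone) (camera adjusted p = 0.0115, or 0.642 with an estimated correlation), with Fgb at -0.99 ± 0.21. Without CD_vehicle 1, which stood 1.75 log2 above the other CD_vehicle libraries in the median of that list, the list median was 0.15 and the call ended (camera adjusted p = 0.221). Saa1 then turned from -2.12 (edgeR adjusted p = 0.144) to 1.36 (edgeR adjusted p = 0.0142). Of the unfolded protein response list, 1 of 18 rose and 1 fell (1 and 1 adjusted over the list alone) (camera adjusted p = 0.416). Without CD_vehicle 1 its median turned from -0.24 to 0.18 and was called (camera adjusted p = 0.0443, or 0.606 with an estimated correlation). Of the male-biased list, 1 of 19 rose and 8 fell (2 and 12 adjusted over the list alone) (camera adjusted p = 7.86e-07, or 0.270 with an estimated correlation): the steroid dehydrogenase Hsd3b5 was 104-fold lower (a call that ended with limma voom, adjusted p = 0.108) and Mup21 fell (-1.84 ± 0.26). CD_vehicle 4 stood 0.97 log2 below the other CD_vehicle libraries in the median of this list, and the median of the comparison without it was −1.57. Of the female-biased list, 1 of 14 rose and 1 fell (2 and 4 adjusted over the list alone) (camera adjusted p = 0.450). Of the CAR and PXR list, 4 of 20 rose and 1 fell (5 and 2 adjusted over the list alone) (camera adjusted p = 0.0906): Cyp3a11 rose from 1105 ± 138 to 3697 ± 846 CPM (3.35-fold) and Cyp2b10 3.97-fold. The call of Cyp2b10 ended with limma voom (adjusted p = 0.141) and with 2 groups in the fit (0.0628). Of the NRF2 list, 6 of 21 rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 1.80e-05, or 0.2496 with an estimated correlation), including Gstm3 (1.81 ± 0.38). In that list CD_vehicle 1 stood at −0.44 log2 and CD_vehicle 4 at 0.40 against the other CD_vehicle libraries, and the call held without either. Of the bile acid list, 4 of 21 rose and 4 fell (6 and 7 adjusted over the list alone) (camera adjusted p = 0.771), with the bile acid importer Slc10a1 lower (-1.48 ± 0.21) and the phospholipid flippase Abcb4 higher (0.75 ± 0.08). Of the glucose list, 0 of 16 rose and 2 fell (0 and 2 adjusted over the list alone) (camera adjusted p = 0.0290, or 0.262 with an estimated correlation), with glucose-6-phosphatase G6pc at -1.17 ± 0.25. That call ended without CD_vehicle 2 (camera adjusted p = 0.0637), without HFD_vehicle 1 (0.0651) and with library totals (0.0805).

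The number of genes called for HFD under vehicle depends on single libraries: it was 956 without CD_vehicle 3, 960 without HFD_vehicle 2 and 881 without HFD_vehicle 4, and 2272 without CD_vehicle 4. Scaling by library totals moved the median log2 fold change of all genes from −0.03 to 0.19, those of the lipogenesis, complement and omega-oxidation lists to −0.27, −0.17 and −0.12 (all still called), and gave 2340 calls, 2052 higher and 288 lower.

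**Figure D4:**
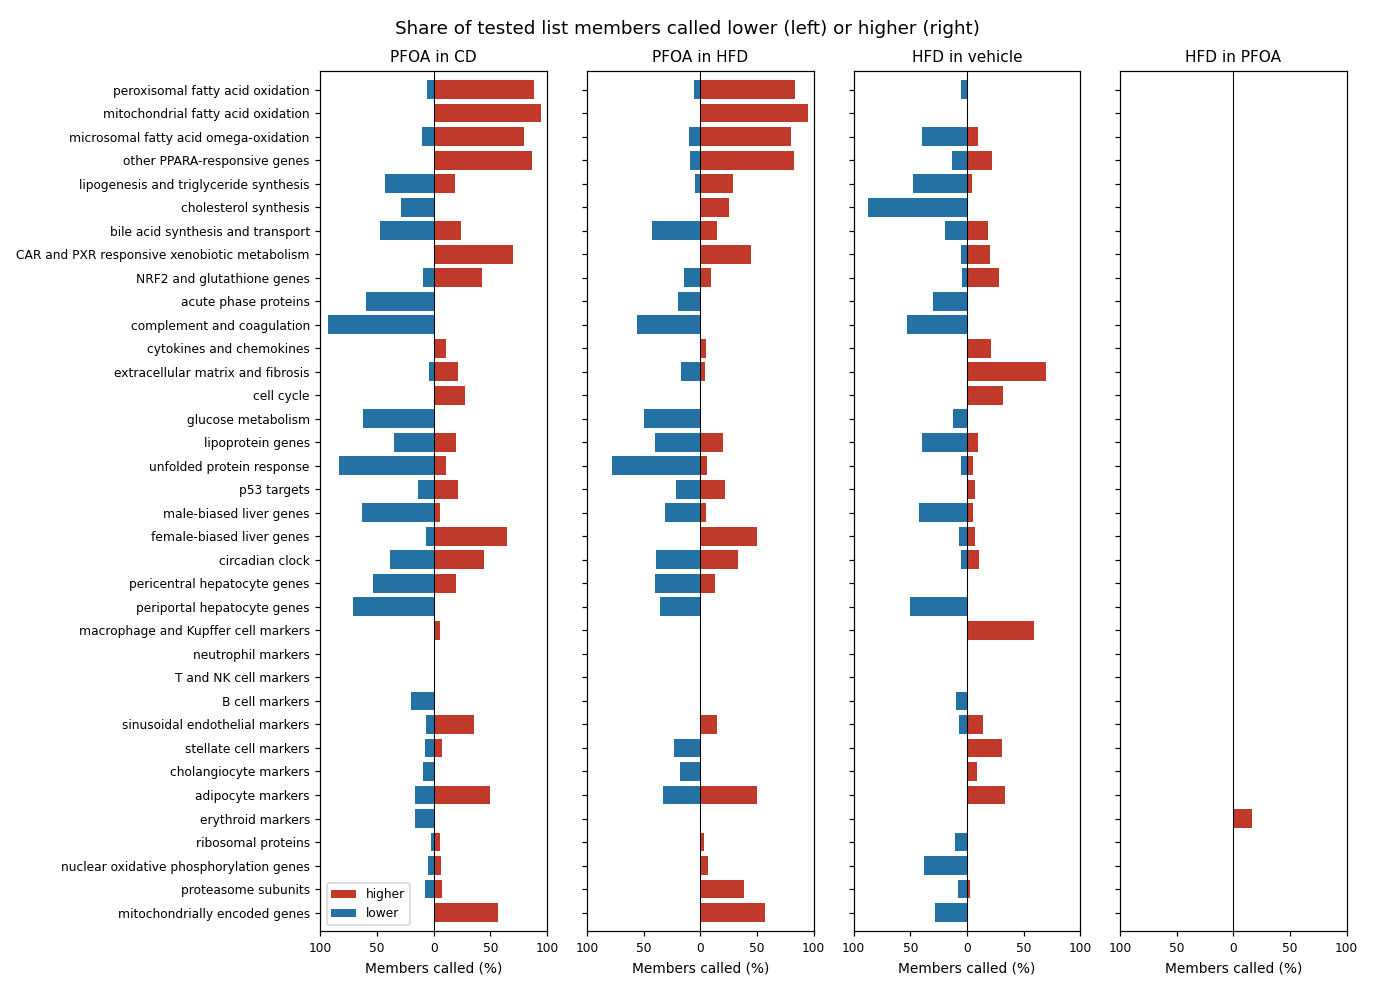
Percent of tested members of 36 gene lists that edgeR called lower (bars to the left of 0) or higher (bars to the right), in 4 panels, 1 for each comparison of 2 groups. Cholesterol synthesis went from 21 of 24 members lower for HFD under vehicle to 0 of 24 for HFD under PFOA, and peroxisomal oxidation had 16 of 18 members higher with PFOA on CD and 15 of 18 on HFD.

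Under PFOA, few single genes were called by edgeR for the high-fat diet. Smad9, a signal transducer of BMP receptors, went from 48.0 ± 10.2 CPM (n = 4) in CD_PFOA to 18.6 ± 1.11 CPM in HFD_PFOA, 2.57-fold lower (log2 fold change -1.36 ± 0.16, edgeR adjusted p = 6.10e-04), and kept its call without any 1 library. The beta-globin gene Hbb-bs rose 3.89-fold (1.96 ± 0.34, edgeR adjusted p = 0.0305). The other called genes were Tpm2 (1.054), Gramd1b (0.86), Samd9l (0.80), Parp14 (0.71) and AW112010 (0.60), all higher, and Hs6st1 (-0.51), lower. Ifih1, an RNA sensor, was the last (0.60, edgeR adjusted p = 0.0305), and was chosen after its values were seen. edgeR called these 9 genes, 7 higher and 2 lower, with 1665 at unadjusted p < 0.05. The count was 4, 2 and 1 without CD_PFOA 2, 3 and 4, 2 and 1 without HFD_PFOA 2 and 4, and 22 without CD_PFOA 1. Without HFD_PFOA 4 the edgeR adjusted p was 0.104 for Hbb-bs, 0.0922 for Tpm2, Gramd1b, Parp14 and AW112010, 0.133 for Samd9l and 0.164 for Hs6st1. DESeq2 called 179 genes (99 higher, 80 lower) and limma voom called 122 higher and 113 lower. Scaling by library totals gave 12 edgeR calls (11 higher, 1 lower).

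Gene groups still leaned with diet under PFOA. The cholesterol synthesis list was lower (median -0.41, camera adjusted p = 6.06e-10, or 0.322 with an estimated correlation). The matrix list (median 0.57, camera adjusted p = 1.49e-07, or 0.322 with an estimated correlation) and the macrophage markers (0.52, adjusted p = 1.08e-05, or 0.343 with an estimated correlation) were higher. So were the cytokine list (0.75, adjusted p = 3.36e-05, or 0.322 with an estimated correlation) and the cell cycle list (0.76, adjusted p = 1.08e-05, or 0.343 with an estimated correlation). In the cell cycle list HFD_PFOA 1 stood at −1.01 log2 and HFD_PFOA 3 at 0.73 against the others of their group. In the macrophage list HFD_PFOA 1 stood at −0.63 and CD_PFOA 3 at −0.87 against their groups. The calls of both lists held without any 1 of these libraries. Of these lists, 0 members were called over all genes tested, and 2 cholesterol, 4 matrix and 2 macrophage genes adjusted over the list alone. The female-biased list was lower (-0.56, adjusted p = 4.52e-04, or 0.322 with an estimated correlation). The erythroid markers were higher (1.13, adjusted p = 0.00110, or 0.322 with an estimated correlation), with 1 of 6 called (3 adjusted over the list alone). Calls that ended without 1 library or more were those of the lists cholangiocyte (median 0.50, camera adjusted p = 0.0175, or 0.322 with an estimated correlation), CAR and PXR (-0.14, adjusted p = 0.0266, or 0.490 with an estimated correlation), clock (-0.14, adjusted p = 0.0273, or 0.322 with an estimated correlation), complement (-0.08, adjusted p = 0.0415, or 0.870 with an estimated correlation) and neutrophil (1.12, adjusted p = 0.0415, or 0.369 with an estimated correlation). The cholangiocyte call ended without CD_PFOA 2 (camera adjusted p = 0.107) and HFD_PFOA 4 (0.0537). The CAR and PXR call ended without CD_PFOA 1 (0.0758) and 4 (0.0748) and HFD_PFOA 3 (0.0653) and 4 (0.167). The clock call ended without CD_PFOA 2 (0.107) and 3 (0.0839) and HFD_PFOA 3 (0.0566) and 4 (0.156). The complement call ended without CD_PFOA 2 (0.180) and 4 (0.0997) and HFD_PFOA 2 (0.264), 3 (0.2003) and 4 (0.318), and with library totals (0.179), where its median was 0.01. The neutrophil call ended without CD_PFOA 1 (0.0758), 3 (0.308) and 4 (0.147) and HFD_PFOA 1 (0.459) and 3 (0.0653), and with library totals (0.196). The remaining lists described so far were not called under PFOA, with camera adjusted p from 0.121 (lipoprotein) and 0.143 (other PPARA-responsive genes) up to 0.975 (peroxisomal and omega-oxidation).

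The interaction asks of each gene whether PFOA acted differently on the 2 diets. Cyp3a11, the main liver P450 for drugs, rose 4.18-fold with PFOA on CD and 1.49-fold on HFD, where its level was already raised (difference in log2 fold change -1.49 ± 0.19, edgeR adjusted p = 0.00244). Lpl showed the same form, 13.8-fold against 4.44-fold (-1.63 ± 0.24, edgeR adjusted p = 0.00971). Cidec rose 5.90-fold on CD against 1.13-fold, not called, on HFD (-2.38 ± 0.39, edgeR adjusted p = 0.0160). Ephx1 (-0.83 ± 0.13) and Il1rn (-1.91 ± 0.33) had smaller responses on HFD as well. Nudt7, a peroxisomal CoA hydrolase, fell on CD and rose on HFD (1.48 ± 0.26). Limch1, chosen after its values were seen, went from 0.559 ± 0.387 CPM in CD_vehicle to 4.24 ± 0.867 in CD_PFOA, and from 12.002 ± 2.23 to 10.9 ± 1.14 CPM on HFD (log2 −3.07 ± 0.41, edgeR adjusted p = 0.00328). edgeR called 31 genes, 10 with a positive and 21 with a negative difference. Scaling by library totals, which moved the median of all genes from 0.02 to −0.10 log2, gave 44 (6 and 38). Tm7sf2 (1.19 ± 0.22), Gadd45a (-1.95 ± 0.40) and Abcb4 (-0.57 ± 0.11) were called as well, but lie near the threshold. Their calls ended without 1 of many libraries, while the differences stayed at 1.06 to 1.32 (Tm7sf2), −2.29 to −1.73 (Gadd45a) and −0.59 to −0.54 (Abcb4). That of Tm7sf2 ended without CD_PFOA 2, HFD_vehicle 2, any HFD_PFOA library and others (edgeR adjusted p = 0.0503 to 0.0832). That of Gadd45a, a growth arrest gene, ended without CD_vehicle 2, any HFD_PFOA library and others (edgeR adjusted p = 0.0614 to 0.103). That of Abcb4 ended without CD_vehicle 2, any CD_PFOA library and others (edgeR adjusted p = 0.0563 to 0.0913). The count ran from 13 without HFD_vehicle 4 or HFD_PFOA 4 to 352 without CD_vehicle 4, with 106 without CD_vehicle 1.

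Gene lists also responded to PFOA in a diet-dependent way under the preset correlation of camera. The cholesterol list had a positive difference (median 0.88, camera adjusted p = 1.84e-13, or 0.406 with an estimated correlation), with 1 member called over all genes tested and 15 adjusted over the list alone. So did the male-biased (1.36, adjusted p = 9.41e-07, or 0.406 with an estimated correlation) and complement lists (0.31, adjusted p = 7.51e-08, or 0.406 with an estimated correlation). Lipogenesis (0.38, adjusted p = 2.69e-04, or 0.527 with an estimated correlation) and omega-oxidation (0.27, adjusted p = 0.00876, or 0.406 with an estimated correlation) were also positive. With library totals the medians of complement, lipogenesis and omega-oxidation shrank to 0.17, 0.249 and 0.14, still called. Negative differences were found for NRF2 and glutathione (-0.30, adjusted p = 9.92e-08, or 0.406 with an estimated correlation) and matrix (-0.48, adjusted p = 6.79e-06, or 0.406 with an estimated correlation). The stellate (-0.28, adjusted p = 5.74e-04, or 0.406 with an estimated correlation), macrophage (-0.32, adjusted p = 7.67e-04, or 0.527 with an estimated correlation), and CAR and PXR lists (-0.20, adjusted p = 5.74e-04, or 0.406 with an estimated correlation) were negative as well. The CAR and PXR call ended when CD_vehicle 1, CD_vehicle 4 and CD_PFOA 1 were left out together (camera adjusted p = 0.144). The cytokine list had -0.25 (adjusted p = 0.0121, or 0.406 with an estimated correlation), a call that ended without HFD_PFOA 1 (camera adjusted p = 0.0591) and with library totals (0.0729). The erythroid markers had 1.06 (adjusted p = 0.0169, or 0.406 with an estimated correlation), a call that ended without CD_PFOA 2 (0.0746). The cell cycle list had -0.20 (adjusted p = 0.0250, or 0.630 with an estimated correlation), a call that ended without CD_vehicle 1 (0.0550), 2 (0.115) or 3 (0.0583), CD_PFOA 2 (0.0560), HFD_vehicle 1 (0.0650) or HFD_PFOA 1 (0.286), and with library totals (0.127). CD_vehicle 1 and CD_vehicle 4 stand apart in the cholesterol, lipogenesis, matrix, stellate and NRF2 lists by the medians given for the diet under vehicle. Calls gained without 1 of these were acute phase (−0.19 without the first, 0.71 without the second; camera adjusted p = 0.0112 and 0.00432, or 0.528 and 0.651 with an estimated correlation), glucose (0.19) and B cell (2.98) without the first (0.0354 and 0.00283, or 0.471 for both), and female-biased without the second (−0.62, 0.00121, or 0.292). In the CAR and PXR list HFD_vehicle 3 stood at 0.48 log2 against the other HFD_vehicle libraries.

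For the question whether PFOA undid the changes made by HFD, the genes called for HFD under vehicle were followed into PFOA on HFD. Of 1561 such genes, 230 were called in the opposite direction and 270 in the same direction. Independent lists would give 129 of each. The opposite count was 111 without HFD_vehicle 2 and 471 when CD_vehicle 1, CD_vehicle 4 and CD_PFOA 1 were left out together. Both comparisons use the HFD_vehicle libraries, which alone gives a correlation of −0.50 across genes in simulations with no effects, against −0.05 in the data. With HFD_vehicle libraries split so that none was shared, 54 to 76 genes were opposite and 71 to 137 in the same direction.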

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

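The tests on library CD_vehicle 4 were chosen after its position was seen; those on CD_vehicle 1 were set before their result was seen. Within each group, each library was compared with the other 3 by Dixon's test on 33 measures, 132 groups in all. This singled out 12 values, where chance alone singles out about 1 in 20 groups.

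Library CD_vehicle 1 had Saa1 at 1255 CPM against 20.7 to 37.2 CPM in the other CD_vehicle libraries, and its 10 most abundant genes held 23.4% of its counts against 29.8 to 30.2%. Saa2 was at 58.0 times, Saa1 at 41.8 times and Lcn2 at 30.9 times the mean of the others. Markers gave no sign of more blood or immune cells. The median of 30 was −0.40 log2 against the other 3, 1 of them high in immune genes. Lyz2 (−0.35), Cd5l (0.03) and C1qa (−0.35) lay within their range and Hbb-bs (−1.76) below. Whether this 1 library carries the fall of the acute phase list with PFOA on CD cannot be told apart from a smaller fall in all, since without it the median went from −1.12 to −0.35 and 10 of 20 members were still lower and 2 higher (camera adjusted p = 0.00183, or 0.495 with an estimated correlation). An acute phase response in this mouse may account for the levels, and no label records its health.

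Library CD_vehicle 4 lay toward the HFD_vehicle libraries, with Col1a1 at 26.6 CPM against 8.84 to 10.49 CPM, and Mki67 at 11.4 CPM against 3.42 to 4.59 CPM, in the other CD_vehicle libraries. On the line between the 2 vehicle groups, where CD_vehicle 1 to 3 lie at −0.14 to 0.21 and HFD_vehicle at 0.803 to 1.07, it lay at 0.588. A wrong label on an HFD_vehicle library, and RNA from such a liver mixed in, are both argued against by the cholesterol synthesis list, whose median was 0.91 log2 above the other CD_vehicle libraries (23 of 24 genes higher), where the HFD_vehicle libraries lay at −0.94 to −0.74. The list varies within the control diet, since CD_vehicle 1 lay at −0.74 on this scale. Limch1 was at 0.555 CPM, like the other CD_vehicle libraries (0.208 to 1.10) and unlike HFD_vehicle (at least 9.99). Gpnmb at 2.18 CPM (0 to 0.281) and Mmp12 at 6.96 CPM (0.183 to 1.31) lay toward HFD_vehicle (at least 15.9 and 39.5), so a small share of such RNA stays open. Mup7 was low at 0.342 CPM (26.1 to 30.5, and a mean of 1.21 in HFD_vehicle), while Sqle was at 137 CPM (17.5 in the others, 3.54 in HFD_vehicle) and the male-biased Hsd3b5 at 1.45 CPM (34.6 to 75.8, and a mean of 0.373 in HFD_vehicle). The same library stood 4.57 log2 above the others in the median of 4 B cell genes and 1.04 in that of the macrophage list. More immune cells in this sample could account for these and were not tested. A state of this mouse that the labels do not record, such as its feeding before the liver was taken, could account for the rest and was not tested.

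Other values singled out were genes with a count in HFD_PFOA 4 (19200, others 18504 to 18616) and the first principal component of HFD_PFOA 1 (41.5, others 49.7 to 50.9). Pdk4 was at 465 CPM in CD_PFOA 1 (464.5, others 269.2 to 295.7). Cpt1a was at 514.6 CPM in CD_vehicle 1 (others 325 to 351.1) and at 507.1 CPM in HFD_PFOA 1 (557.2 to 563.1). HFD_PFOA 1 also had Cyp3a11 at 5942 CPM (5300.5 to 5384), Cyp8b1 at 302.3 CPM (146.2 to 154.3) and Saa1 at 29.7 CPM (9.62 to 11.4).

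The PFOA response differed between the diets, by the interaction test, for 31 genes and 16 gene lists. The lists called were 0 with an estimated correlation and 0 with fry, and the genes 13 to 352 without single libraries and 584 without 3 libraries. The named genes among them were Cidec (difference in log2 fold change −2.38), Tm7sf2 (1.19), Abcb4 (−0.57), Cyp3a11 (−1.49), Ephx1 (−0.83), Il1rn (−1.91), Lpl (−1.63), Gadd45a (−1.95) and Nudt7 (1.48). The calls of Tm7sf2, Abcb4 and Gadd45a ended without single libraries (edgeR adjusted p up to 0.0832, 0.0913 and 0.103).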

How the results depend on the processing

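Leaving out 3 libraries together (CD_vehicle 1, CD_vehicle 4 and CD_PFOA 1), and the list, overlap and reversal results without single libraries and under other scalings, were chosen after seeing the data. PFOA in CD gave 3072 to 3971 calls without single libraries and 2602 to 4033 otherwise, against 3656. PFOA in HFD gave 1990 to 2184 and, with limma voom, 3834, against 2476. HFD in vehicle gave 881 to 2272 without single libraries, 896 with 2 groups in the fit, 2340 with library totals and 2509 without the 3 libraries, against 1561. HFD in PFOA gave 1 to 22 without single libraries, 179 with DESeq2, 2.4e+02 with limma voom (122 higher and 113 lower), 2.2e+02 with no filter (142 and 83), 129 with 2 groups in the fit and 426 without the 3 libraries, against 9. The interaction gave 13 to 352 without single libraries, 223 with DESeq2, 160 with limma voom, 290 with no filter and 584 without the 3 libraries, against 31. CD_vehicle libraries bear on HFD in PFOA only through the filter, scaling and spread shared in the fit. Which of these acted, and other causes, were not tested. Gene lists called, with camera at an estimated correlation, were 7, 5, 0, 0 and 0 in the order above. The test fry called 1 for HFD in PFOA and 0 for the interaction, and does not compare a list with other genes. Without single libraries the lists called were 16 to 18, 16 to 19, 18 to 21, 13 to 19 and 14 to 19. The overlap of PFOA responses was 1774 genes, 1115 at adjusted p under 0.01 and 1497 to 1727 without single libraries. The count of HFD changes called in the opposite direction with PFOA was 230, 111 to 276 without single libraries and 471 without the 3 libraries. With the HFD_vehicle libraries split between the comparisons it was 54, 58, 62, 74, 76 and 73, from 2 libraries per mean. Saa1 in HFD in vehicle ran from −2.51 to 1.36 without single libraries and was 1.55 without the 3; CD_vehicle 1 turns it. Of the named genes called among the largest changes, the index genes and the called lists, 75 of 84, 76 of 86, 57 of 88, 1 of 8 and 5 of 7 kept their call in every alternative run, and 0 reversed. Calls of genes named in the report that ended with other settings included Birc5 in PFOA in CD (adjusted p = 0.0872) and HFD in vehicle (0.0665), Fasn (0.0752) and mt-Nd1 (0.0553) in PFOA in CD, all with 2 groups in the fit. Saa1 in PFOA in CD ended with limma voom (0.105), without the 3 libraries (0.153) and with DESeq2, which gave no adjusted p. In HFD in vehicle, Hsd3b5 (0.108) and Cyp2b10 (0.141) ended with limma voom. Hs6st1 in HFD in PFOA ended with library totals (0.0923), Gadd45a in the interaction with limma voom (0.198), and Cdkn1a in PFOA in CD without the 3 libraries (0.0946). For named genes of lists not called, fits without single libraries were examined after seeing the data. In the simulated data, where few genes changed, 1.5-fold changes were mostly missed (23.9%, 47.8%, 22.4% and 43.3% called in the 4 contrasts of 2 groups). This need not hold where more genes change. No paired analysis was possible, as replicate numbers pair no mice.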

Other observations

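The list results without single libraries were chosen after seeing the data. The gene lists of this part were fixed before the data were examined, and the tests of explanations before their results were seen. Clock and zonation genes changed with PFOA on both diets. Of the circadian clock list, 8 of 18 rose and 7 fell (9 and 7 adjusted over the list alone) with PFOA on CD, and 6 of 18 rose and 7 fell (7 and 7 adjusted over the list alone) on HFD, with no direction of the list as a whole (camera adjusted p = 0.751 and 0.668). The output gene Dbp rose 22.9-fold on CD and 5.58-fold on HFD, and the core repressor Cry1 fell (-2.06 ± 0.24 and -1.60 ± 0.24, log2 fold change ± SE), as did the activator Arntl (-1.85 ± 0.17 and -0.96 ± 0.16). The time of day at which livers were taken is not given in the sources used here. With HFD under vehicle, 2 of 18 rose and 1 fell (4 and 4 adjusted over the list alone) (camera adjusted p = 0.8293). Genes of both ends of the liver lobule fell with PFOA. Of the pericentral list, 3 of 15 rose and 8 fell (3 and 8 adjusted over the list alone) on CD (camera adjusted p = 0.00671, or 0.526 with an estimated correlation). On HFD, 2 of 15 rose and 6 fell (3 and 7 adjusted over the list alone) (camera adjusted p = 4.31e-04, or 0.440 with an estimated correlation). HFD_PFOA 1 stood 0.71 log2 above the other HFD_PFOA libraries in the median of the pericentral list, and the call on HFD held without it. Of the periportal list, 0 of 14 rose and 10 fell (1 and 10 adjusted over the list alone) on CD (camera adjusted p = 2.06e-04, or 0.308 with an estimated correlation). On HFD, 0 of 14 rose and 5 fell (0 and 6 adjusted over the list alone) (camera adjusted p = 9.58e-04, or 0.455 with an estimated correlation), among them the urea cycle enzymes Cps1 (-1.36 ± 0.19 on CD and -1.11 ± 0.19 on HFD) and Asl (-1.17 ± 0.16 and -0.98 ± 0.16). In the periportal list CD_PFOA 3 stood at 0.40 log2, CD_PFOA 1 at −0.35, CD_vehicle 3 at 0.34 and CD_vehicle 4 at −0.31 against their groups, and the call on CD held without any 1 of them. With HFD under vehicle, 0 of 14 rose and 7 fell (0 and 8 adjusted over the list alone) of the periportal list (camera adjusted p = 2.63e-04, or 0.270 with an estimated correlation), whose median went from -0.46 to −0.24 with library totals. In the same comparison 0 of 15 pericentral genes were called by edgeR (camera adjusted p = 0.124). Under PFOA both lists were lower with HFD (camera adjusted p = 9.65e-04, or 0.369 with an estimated correlation, pericentral; camera adjusted p = 4.85e-04, or 0.343 with an estimated correlation, periportal).

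Relative to other genes, those of the respiratory chain and of protein synthesis were lower with HFD under vehicle. Of nuclear oxidative phosphorylation genes, 0 of 84 rose and 32 fell (1 and 48 adjusted over the list alone) (camera adjusted p = 1.40e-15, or 0.2496 with an estimated correlation), among them Cox7b (-0.52 ± 0.10). For ribosomal proteins, 0 of 88 rose and 9 fell (0 and 14 adjusted over the list alone) (camera adjusted p = 1.37e-05, or 0.0566 with an estimated correlation), among them Rpl30 (-0.74 ± 0.16). With library totals the medians shrank from -0.32 to −0.10 and from -0.25 to −0.03, still called (camera adjusted p = 1.36e-09 and 4.80e-05), and members such as Uqcrh and Rpl32 lost their edgeR calls (adjusted p = 0.0623 and 0.334). Both were also lower with HFD under PFOA (camera adjusted p = 8.36e-11, or 0.343 with an estimated correlation, oxidative phosphorylation; camera adjusted p = 2.34e-05, or 0.199 with an estimated correlation, ribosomal), as were the mitochondrially encoded genes (camera adjusted p = 9.37e-04, or 0.369 with an estimated correlation). With library totals those medians were −0.08, −0.07 and −0.13. Of proteasome subunits, 1 of 39 rose and 3 fell (1 and 9 adjusted over the list alone) with HFD under vehicle (camera adjusted p = 6.46e-04, or 0.306 with an estimated correlation). With library totals the median turned from -0.19 to 0.03 and the call ended (camera adjusted p = 0.121). With PFOA on HFD, 15 of 39 rose and 0 fell (19 and 2 adjusted over the list alone) of the proteasome list (camera adjusted p = 0.00139, or 0.463 with an estimated correlation), among them Psmd4 (0.81 ± 0.11). On the same diet, 6 of 84 rose and 0 fell (4 and 0 adjusted over the list alone) of the oxidative phosphorylation list (camera adjusted p = 0.00499, or 0.703 with an estimated correlation), among them Ndufab1 (1.37 ± 0.14). In the interaction both had positive differences (camera adjusted p = 0.00138, or 0.508 with an estimated correlation, proteasome; camera adjusted p = 7.78e-04, or 0.663 with an estimated correlation, oxidative phosphorylation). With library totals the medians shrank from 0.16 and 0.15 to 0.02 each (camera adjusted p = 0.0496 and 0.0394). Of the mitochondrially encoded genes, 4 of 7 rose and 0 fell (4 and 0 adjusted over the list alone) with PFOA on CD and 4 of 7 rose and 0 fell (4 and 0 adjusted over the list alone) on HFD (camera adjusted p = 0.0877 and 0.0504), with mt-Nd1 at 0.44 ± 0.12 and 0.62 ± 0.12. Mitochondrially encoded genes held 9.79 to 13.6% of counts in the vehicle libraries and 13.5 to 17.8% in the PFOA libraries, and ribosomal RNA genes 0.152 to 0.227% and 0.265 to 0.404%. Some genes may be counted in both shares, so these cannot tell whether the mitochondrial rise is technical in part, which stays open. With HFD under vehicle, 0 of 7 rose and 2 fell (0 and 4 adjusted over the list alone) (camera adjusted p = 0.0290, or 0.515 with an estimated correlation), a call that ended without any 1 of 5 libraries, among them CD_vehicle 2 (0.111), and with library totals (0.0908). Of the p53 targets, 3 of 14 rose and 2 fell (3 and 5 adjusted over the list alone) with PFOA on CD, where Gadd45a rose 17.5-fold and the cell cycle inhibitor Cdkn1a fell (-1.03 ± 0.23), and 3 of 14 rose and 3 fell (3 and 3 adjusted over the list alone) on HFD, with Cdkn1a at -1.81 ± 0.24 (camera adjusted p = 0.693 and 0.464). With HFD under vehicle, 1 of 14 rose and 0 fell (5 and 0 adjusted over the list alone) (camera adjusted p = 0.0431, or 0.298 with an estimated correlation), a call that ended without CD_vehicle 2 (0.165) or 4 (0.0549) or HFD_vehicle 1 (0.0865) or 3 (0.0509). In the interaction the p53 list had a negative difference (-0.16, camera adjusted p = 0.0463, or 0.437 with an estimated correlation). That call ended without many single libraries, among them CD_vehicle 2 (0.226) and CD_PFOA 2 (0.103).

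The diet changed fewer genes under PFOA (9) than under vehicle (1561), and 3 explanations were weighed. A larger spread between the PFOA libraries is argued against. The slope of the diet effect under PFOA on that under vehicle, across 12373 genes with no library shared, was 0.380 ± 0.140 (jackknife SE, 0.316 to 0.457 without single libraries), where 1 would be needed. The biological coefficient of variation was 0.189 in the PFOA pair and 0.222 in the vehicle pair. PFOA on CD had a slope of 0.70016 ± 0.123 (0.645 to 0.770 without single libraries) on the diet effect. PFOA on HFD had 0.0804 ± 0.119. These fix the 0.380 and are no separate test. They place the move in control livers, toward fat-fed ones. GC content and transcript length are argued against as its source, since removing their trend from each library left the CD slope at 0.69982. A technical difference shared by all 4 CD_vehicle libraries stays open, since no batch is labelled, and genes are not independent replicates.

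Chance assignment of mice is argued against, not excluded, for contrasts of 2 groups, as 35 splits give no share under 0.0286. Only the real split reached its count: 3656 calls for PFOA in CD (highest other split 25) and 2476 for PFOA in HFD (0). HFD in vehicle gave 1561 (56, with CD_vehicle 4 and HFD_vehicle 3 exchanged) and HFD in PFOA 9 (1). For the interaction chance stays open. Of 100 draws, 2, the real one among them, gave at least the real 31, but nearly all moved vehicle libraries, which puts the diet difference under vehicle within the groups and widens their spread. The other of these 2, which left them in place and exchanged CD_PFOA 2 and HFD_PFOA 3, gave 58.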
